A study of Mus musculus with 6 samples.

How the data were processed

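Total RNA of 6 cultures or samples of the mouse mammary carcinoma line 4T1 was isolated with a column kit and turned into libraries with a stranded kit for mRNA, per the labels' protocols. Groups were taken from the sample titles: WT (mock transfected), shRNA1 and shRNA3, with 2 libraries each. The authors deposited 1 table per library with a gene symbol and a value. The unit is not written in the tables. It was taken to be FPKM, fragments per length of transcript and mapped fragments of the library, since the submitters' processing notes name Cufflinks 2.2.1, and the deposited values are not whole, have 3 decimals and do not sum to a common total. The notes also name TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and the build mm10, without roles or options. The annotation, the strand setting and the treatment of reads that fit several genes are not given in the sources used here. FPKM values are relative to the mapped total of a library, so a rise of abundant genes lowers all others, and genes with near-identical copies can lose or gain reads.

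Of the 24346 symbols, 98.2% matched 1 gene of GENCODE mouse release 21 on GRCm38, the same assembly as mm10, from which coordinates, gene types, transcript lengths and GC content were taken. Symbols that no single gene matched, such as Ddit3, are given without coordinates. The most frequent ratio between libraries of values from 0.1 to 0.6 FPKM gave the relative depth. With it, the values of AU021063, Il6 and the short RNA genes named were whole multiples of the value of 1 fragment, within 0.05 of a whole number, which gave their fragment numbers. A330009N23Rik gave no such numbers. The absolute depth is not known. Intervals at a level of 95% are exact binomial intervals on these fragment numbers and cover counting error only, since copies of 1 molecule cannot be recognised.

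Values were transformed to log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 6 libraries were kept, which left 11079. A means model with the 3 groups was fitted to all 6 libraries with limma 3.58.1 (R 4.3.3) with a trend in the prior variance, with 3 residual and 4.96 prior degrees of freedom. The contrasts were the mean of both hairpins against WT, each hairpin against WT, and shRNA3 against shRNA1, all two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. A count test was not used because the files hold no counts. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it and with fry, Benjamini-Hochberg adjusted over the lists of a contrast. Of 28 lists 24 had at least 5 members that passed the filter. They cover the route named in the series title (study axis), ERK pathway output, the ATF4 and amino acid response, endoplasmic reticulum chaperones, mesenchymal, epithelial, protease and adhesion genes, DNA replication, mitosis, glycolysis and hypoxia, oxidative phosphorylation, STAT3, NF-kB, interferon, MHC class I, p53, NRF2, sterol synthesis, YAP, TGF-beta, ribosomal proteins, and markers of other cells and of RNA quality. Lists, tests, the rule for named genes and the alternatives were fixed before the data were examined, apart from those said to be added or chosen later. The exact binomial tests on the fragments of AU021063 were not part of that plan. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for loading, exact tests and figures.

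The rule selects the members of the study axis, the 8 largest rises and 8 largest falls over both hairpins and the 4 and 4 of the other contrasts, and up to 3 called members of each list with the largest change over both hairpins, or up to 2 with the highest expression where none was called. The ranked genes had to pass the threshold with all libraries of one side above or below those of the other, and, over both hairpins, with the same sign in each. Of 4567 genes that met this for both hairpins, 151 were models without a given name and were counted, not named. Chance alone separates 2 against 4 libraries in 13.3% of genes and 2 against 2 in 33.3%. Of the genes that this rule selects 4 are not reported here, and none were put in their place. Genes outside this rule are said to have been picked after their values were seen.

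The fit was tested on simulated data: for the 11079 genes with 200 of them changed, the contrast of both hairpins against WT recovered 94.0% of changes of 0.5 on the log2 scale and 100% of changes of 1 and 2, and 4.85% of its calls were unchanged genes. For shRNA1 and shRNA3 against WT 8.06% and 8.76% of the calls were unchanged genes, above the 5% that the adjustment aims at, and 3.41% for shRNA3 against shRNA1. Agreement of the hairpins was compared with 100 draws of all 6 libraries with no effect, in which both hairpin groups shared the drawn WT libraries. The alternatives were pseudocounts of 0.1 and 0.5, no filter and a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, rescaling each library to the same total, no trend, a robust prior, array weights, only the groups compared in the fit, the replicate number as a block, each library left out in turn, and a minimum change of 2-fold. A fit without miRNA and snoRNA genes was added after seeing the data.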

Results

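RNA sequencing was performed on 6 libraries of 4T1 cells, a mouse mammary carcinoma line that spreads to distant organs when grafted into mice. The libraries formed 3 groups of 2. WT cells had been mock transfected, and the cells named shRNA1 and shRNA3 carried either of 2 short hairpin RNAs against the long noncoding RNA AU021063. The labels name no culture with a non-targeting hairpin. They also do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Each library gave 1 value in FPKM for each of 24346 gene symbols. The values summed to between 560862 and 604022 FPKM per library, and between 10998 and 11106 symbols reached 1 FPKM. The ratios between low values put the depth of the libraries at 86.8% to 105% of that of WT replicate 1, so depth differed little between them. For genes with a mean of at least 10 FPKM, the 2 libraries of a group differed by a median of 4.47% in WT, 4.40% in shRNA1 and 4.32% in shRNA3. In a principal component analysis the first component, with 46.2% of the variance, ordered WT, shRNA1 and shRNA3, and the second, with 26.1%, set shRNA1 apart. All group values below are means ± SD of n = 2 libraries in FPKM, and folds of single genes are ratios of these means. All log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Counts of genes that changed at least 2-fold rest on that scale, as a log2 change of at least 1 in size, and not on ratios of means.

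The first question was whether the hairpins lowered their target. AU021063 (ENSMUSG00000115944.1) is annotated as a long intergenic noncoding RNA on chromosome 15, positions 101221247 to 101222155, plus strand, of the mm10 (GRCm38) mouse genome. It lies wholly within A330009N23Rik, an antisense gene on the minus strand at positions 101221195 to 101225186, and whether the authors' quantification used strand is not given in the sources used here, so reads of the overlapping pair may not have been separated. AU021063 was at 1.82 and 1.67 FPKM in the WT libraries. It was at 1.04 and 0.572 FPKM with shRNA1 and at 0.785 and 0 FPKM with shRNA3. The mean of the 4 knockdown libraries was 34.4% of the WT mean, with 46.3% for shRNA1 and 22.5% for shRNA3. All 4 knockdown libraries lay below both WT libraries, with an exact permutation test giving p = 0.133 (two-sided), the smallest value that 4 against 2 libraries allow. The values rest on few sequenced fragments: 11 and 10 in WT, 6 and 3 with shRNA1, 5 and 0 with shRNA3. From these numbers and the relative depths, the rate in the knockdown libraries was 35.2% of WT (95% exact binomial interval 16.6% to 72.6%, p = 0.00225, two-sided). For shRNA1 the rate was 46.9% (18.9% to 107%, exact p = 0.0663), and for shRNA3 it was 24.3% (7.16% to 66.2%, exact p = 0.00253). A count of 0 in shRNA3 replicate 2 allows up to 3 fragments, or 0.555 FPKM. These intervals and the limit cover counting error only, and the binomial tests were not among those fixed beforehand. AU021063 averaged 0.983 FPKM over the 6 libraries, so it did not pass the filter of 1 FPKM and was not tested with limma.

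The series title places AU021063 downstream of IL-6 and Arid5a and upstream of Trib3 and the Mek/Erk pathway, so genes of that route were followed by name. Trib3, a pseudokinase induced by ATF4 under stress (chromosome 2, 152337422 to 152344032, minus strand), fell from 132 ± 5.69 FPKM in WT to 25.4 ± 1.16 with shRNA1 and 61.2 ± 1.72 with shRNA3, a 5.20-fold and a 2.15-fold decrease. Its log2 change over both hairpins was -1.71 ± 0.05 (SE, limma, Benjamini-Hochberg adjusted p = 2.88e-07). Stat3, the transcription factor activated by IL-6, rose from 52.5 ± 0.0141 to 67.4 ± 0.199 and 68.1 ± 0.465 FPKM. Of the kinases of the pathway given here, Map2k1 (Mek1) rose 1.30-fold over both hairpins, Mapk3 (Erk1) 1.24-fold and Braf 1.32-fold. The call of Braf ended without WT replicate 2 (log2 change 0.27, adjusted p = 0.0569; range over all settings 0.00341 to 0.102). Map2k2, Akt1, Arid5a, Il6ra, Il6st and Rfwd2 did not pass the test over both hairpins, with log2 changes from -0.16 for Map2k2 to 0.03 for Rfwd2. Rescaling to the same total made lower calls of Map2k2 (-0.23, adjusted p = 0.0141), Il6st (-0.16, 0.0210) and Akt1 (-0.14, 0.0468), as did leaving out shRNA1 replicate 1 for Map2k2 (0.00729) and quantile normalization for Il6st (0.0257). Il6st, the shared signalling subunit of the IL-6 receptor, was lower with shRNA1 (log2 change -0.23, adjusted p = 0.00566), and its difference between the hairpins passed the test (0.28, adjusted p = 0.00202). Il6 itself was below the filter, at 0.419 and 0.212 FPKM in WT, 1.69 and 1.29 with shRNA1, and 0.531 and 1.17 with shRNA3, or 9, 39 and 23 fragments per group. Of the 13 tested members 4 rose and 2 fell, with the same numbers when adjusted over the list alone. The list as a whole did not pass camera (adjusted p = 0.933; adjusted p = 0.935 with an estimated correlation), which gave it an upward direction although its median (-0.01) and mean (-0.09) were negative. This list was taken from the series title and is not independent evidence.

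**Figure D1:**
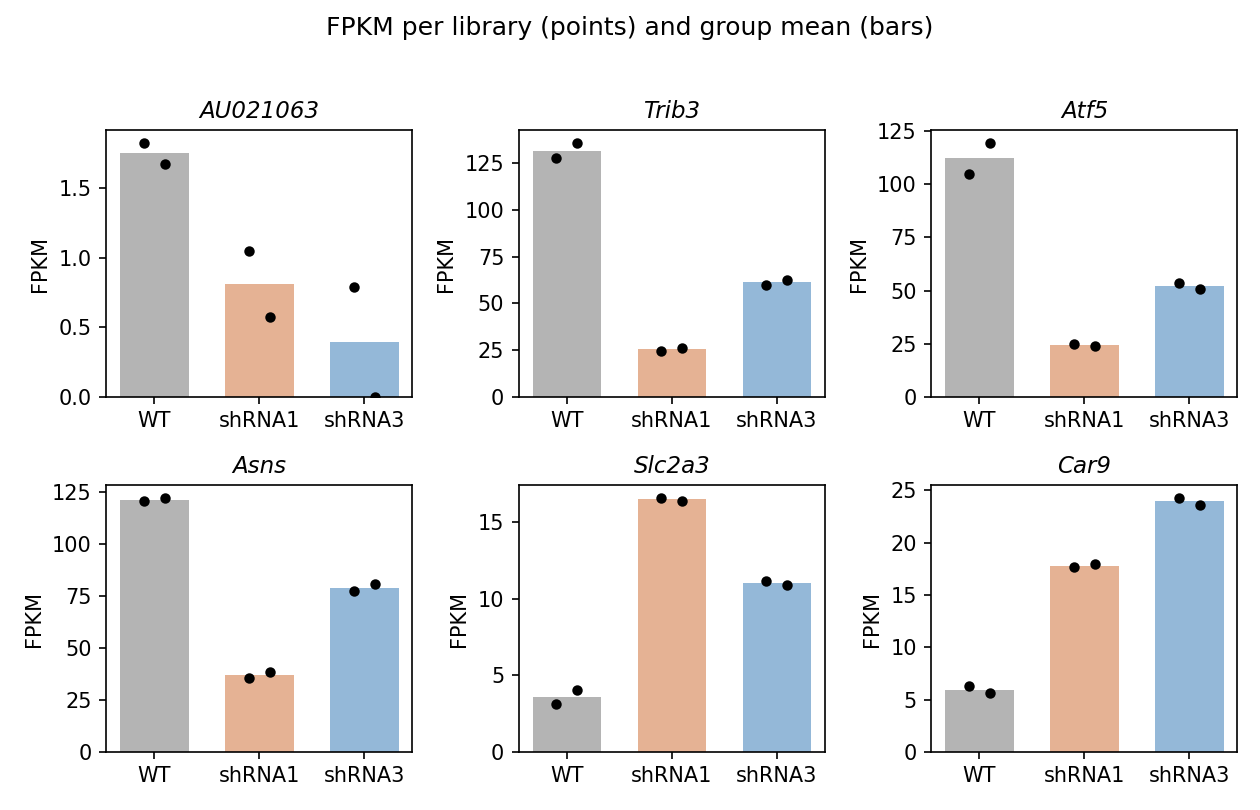
FPKM of AU021063, Trib3, Atf5, Asns, Slc2a3 and Car9 in each library (points) with the mean of each group of 2 libraries (bars), for WT, shRNA1 and shRNA3; each panel has its own linear axis from 0. Trib3, Atf5 and Asns lay lower in all 4 knockdown libraries than in WT, with the lower values in shRNA1, and Slc2a3 and Car9 lay higher.

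The main comparison set the mean of the 2 hairpins against WT. A gene that changed with 1 hairpin alone can also be called in it, and calls by both hairpins are counted further below. Genes are ranked by their change on the log2(FPKM + 1) scale, on which low genes rank lower than by the ratio of means. The largest rises of named protein-coding genes on this scale were those of Krt19, a keratin of simple epithelia, Nos2, the inducible nitric oxide synthase, and Ptx3, a secreted pattern recognition protein. Krt19 went from 1.56 ± 0.324 FPKM in WT to 20.1 ± 0.468 with shRNA1 and 12.8 ± 0.605 with shRNA3, Nos2 from 4.29 ± 0.148 to 25.6 ± 0.887 and 30.4 ± 0.634, and Ptx3 from 3.05 ± 0.229 to 13.5 ± 0.228 and 26.1 ± 0.876. Gadd45b, a stress-induced gene, rose 6.40-fold over both hairpins, Steap4, a metalloreductase, 9.14-fold, and Cyr61, a matrix protein and YAP target, 4.65-fold. The largest falls on this scale were those of Ifi27l2a, an interferon-induced gene, from 27.9 ± 3.77 to 4.28 ± 0.868 and 11.9 ± 1.65 FPKM, of Trib3, and of Atf5, a transcription factor of the ATF4 response, from 112 ± 10.1 to 24.2 ± 0.715 and 52.3 ± 2.03. S100a8, Inmt and Pi16 followed at log2 changes of -1.54, -1.48 and -1.45. S100a8 fell 1.27-fold with shRNA1 and 7.20-fold with shRNA3, and its call over both was lost when the 4 knockdown libraries were fitted as 1 group. By the ratio of means Steap4 stood above Nos2 (6.52-fold) and Ptx3 (6.50-fold), and Inmt (3.16-fold) above Trib3 (3.04-fold) and Atf5 (2.93-fold). Over both hairpins 2672 of the 11079 genes tested were higher and 2866 lower than in WT (limma, Benjamini-Hochberg adjusted p under 0.05), of which 97 and 24 changed at least 2-fold. The median size of a called change was 0.30 on the log2 scale. With the 4 knockdown libraries fitted as 1 group, so that differences between the hairpins count as spread, the numbers were 798 and 715. With each library rescaled to the same total, 34.7% of the called genes were higher, against 48.2% on the values as deposited.

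The ranking was led by short RNA genes whose values rest on a few fragments. Mir8094 was listed at 0 in both WT libraries and rested on 1, 2, 1 and 2 fragments in the knockdown libraries. Mir1291 rested on 1 fragment in each WT library and was listed at 0 in all 4 knockdown libraries. Snora44 rested on 1 fragment in each WT library and in shRNA3 replicate 1, and its call ended without either WT library (adjusted p = 0.0825 without replicate 1 and 0.0708 without replicate 2; range over all settings 2.58e-08 to 0.171). Fragments of this number, which the library preparation for mRNA does not select for, cannot show a change at this depth, and no fold is given for them. Without miRNA and snoRNA genes, a choice made after seeing the data, 2741 genes were higher and 2936 lower, and the ranking continued with Dcn, the gene of the proteoglycan decorin, among the rises and with Cth, an enzyme of cysteine synthesis, and Cyp24a1, the vitamin D 24-hydroxylase, among the falls. Dcn rose from 10.7 ± 0.365 to 35.9 ± 1.57 and 45.3 ± 1.20 FPKM. Cth fell from 19.2 ± 0.237 to 7.54 ± 0.423 and 5.44 ± 0.0389 FPKM.

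Genes of the ATF4 and amino acid response fell together with both hairpins. Of 31 tested members 28 fell and 1 rose (Ddit4, an inhibitor of mTORC1 that hypoxia also induces), with the same numbers when adjusted over the list alone. Besides Trib3 and Atf5, the glycine transporter gene Slc6a9 fell from 31.8 ± 2.19 FPKM to 11.3 ± 0.831 and 16.7 ± 0.339. Atf4 itself and Asns, the asparagine synthetase gene, both picked after their values were seen, fell 1.89-fold and 2.10-fold over both hairpins. The median log2 change of the list was -0.68 (camera adjusted p = 4.37e-15; adjusted p = 0.130 with an estimated correlation). The list called endoplasmic reticulum chaperones here also holds other genes of the unfolded protein response. Of its members 14 of 22 fell and 0 rose over both hairpins, Hyou1 (1.61-fold lower), Dnajb11 (1.44-fold lower) and Manf (1.39-fold lower) among them. The median was -0.20 (camera adjusted p = 7.15e-04, and 0.207 with an estimated correlation). The list did not pass with shRNA3 alone, where 10 fell and 4 rose (median -0.11, camera adjusted p = 0.153), against 15 falls and 0 rises with shRNA1 (median -0.21, adjusted p = 2.25e-07; adjusted p = 0.0754 with an estimated correlation).

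Genes of glycolysis and of the response to hypoxia rose. Of 30 tested members 29 rose and 0 fell, also when adjusted over the list alone, with a median log2 change of 0.88 (camera adjusted p = 1.88e-20; adjusted p = 0.0693 with an estimated correlation). Slc2a3, a glucose transporter gene, rose from 3.59 ± 0.654 FPKM in WT by 4.58-fold with shRNA1 and 3.06-fold with shRNA3. Car9, a carbonic anhydrase induced by HIF-1, rose from 5.94 ± 0.499 to 17.8 ± 0.187 and 23.9 ± 0.450, and Adm (adrenomedullin) from 6.73 ± 0.426 to 20.5 ± 2.35 and 21.6 ± 0.528. Among the abundant glycolytic enzymes, picked after their values were seen, Pgk1 rose 2.45-fold over both hairpins, Ldha 1.97-fold and Gapdh, often used as a reference gene, 1.88-fold. Of the sterol synthesis genes 23 of 24 rose and 0 fell, with a median of 0.42 (camera adjusted p = 2.05e-10; adjusted p = 0.0693 with an estimated correlation). Fdps rose 1.80-fold, Hmgcs1 1.76-fold and Lss 1.79-fold, all of them enzymes of the mevalonate and lanosterol steps. By hairpin, 24 of 24 sterol synthesis genes rose with shRNA1 (median 0.62), against 11 of 24 with 1 fall for shRNA3 (median 0.18).

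Several lists tied to matrix, adhesion and cell shape were also higher. Of the mesenchymal genes 14 of 20 rose and 0 fell, with Tgfb2 (2.44-fold) and Tgfbi (3.19-fold) among them and a median of 0.43 (camera adjusted p = 3.48e-06; adjusted p = 0.132 with an estimated correlation). Epithelial and keratin genes did not move the opposite way: 8 of 17 rose, Krt19 and Dsp (2.15-fold higher) among them, and 3 fell, with a median of 0.14 (camera adjusted p = 0.0294; adjusted p = 0.349 with an estimated correlation). The call of the list of epithelial and keratin genes ended without shRNA1 replicate 1 (adjusted p = 0.0597), with quantile normalization (0.0684) and with a filter at a mean of 5 FPKM (0.0664), with a range over all camera settings of 0.0159 to 0.349; fry, which tests the list on its own and not against other genes, gave 0.00258. With shRNA3 alone this list did not pass (7 rose and 4 fell, median 0.18, camera adjusted p = 0.241), and with shRNA1 alone it did (10 rose and 1 fell, median 0.17, adjusted p = 2.75e-04; adjusted p = 0.205 with an estimated correlation). Among matrix proteases and their inhibitors 13 of 24 rose and 3 fell (median 0.18, camera adjusted p = 0.00126; adjusted p = 0.132 with an estimated correlation). Mmp9, a gelatinase, rose from 70.2 ± 2.46 FPKM to 207 ± 5.06 and 208 ± 3.58, and the matrix enzyme genes Adamts1 and Hpse rose 2.81-fold and 2.06-fold. Of the integrin and adhesion genes 12 of 18 rose and 2 fell, with Itga7 (3.48-fold higher), Vcl (1.98-fold higher) and Itgb4 (1.57-fold lower) changing most, and a median of 0.20 (camera adjusted p = 0.00211; adjusted p = 0.221 with an estimated correlation). Of the YAP and TEAD targets 12 of 17 rose and 1 fell, with Cyr61, Ankrd1 (1.95-fold) and F3 (1.82-fold) in front and a median of 0.31 (camera adjusted p = 1.54e-05; adjusted p = 0.207 with an estimated correlation).

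Targets of STAT3 rose in 15 of 20 cases and fell in 2 (median 0.32, camera adjusted p = 1.54e-05; adjusted p = 0.139 with an estimated correlation). The acute phase gene Lbp rose 2.32-fold, Socs3, the feedback inhibitor of this pathway, 1.73-fold and Il4ra 1.52-fold. Mitotic genes rose in 15 of 25 cases with 0 falls, by small amounts: Aurkb rose 1.37-fold, Prc1 1.34-fold and Top2a 1.31-fold, and the median was 0.19 (camera adjusted p = 7.12e-06; adjusted p = 0.132 with an estimated correlation). Of the genes of MHC class I antigen presentation 10 of 19 rose and 4 fell, among them the proteasome subunits Psmb9 (2.46-fold higher) and Psmb8 (1.35-fold higher) and Cd274, the gene of PD-L1 (2.36-fold higher), with a median of 0.19 (camera adjusted p = 0.0294; adjusted p = 0.416 with an estimated correlation, and 0.106 with quantile normalization; range over all camera settings 0.0136 to 0.416, and 0.00540 with fry, on the list alone). The MHC class I list did not pass with shRNA1 alone, where 5 rose and 3 fell (median 0.07, or -0.02 with quantile normalization; camera adjusted p = 0.496), and passed with shRNA3, where 11 rose and 4 fell (median 0.38, adjusted p = 0.00313; adjusted p = 0.324 with an estimated correlation). Of the interferon response genes 18 of 36 fell and 4 rose (median -0.19, camera adjusted p = 0.00528; adjusted p = 0.144 with an estimated correlation), with Irf7 (1.70-fold lower), Bst2 (1.64-fold lower) and Isg15 (1.63-fold lower) in front; with shRNA3 alone the list did not pass (median 0.02, adjusted p = 0.480). The cytoplasmic ribosomal protein genes rose in 22 of 36 cases with 0 falls (median 0.13, camera adjusted p = 9.50e-06; adjusted p = 0.349 with an estimated correlation), but with quantile normalization the median was -0.04. With shRNA1 alone 4 of 36 rose and 1 fell and the list did not pass (median 0.06, camera adjusted p = 0.0745), against 31 of 36 with 0 falls for shRNA3 (median 0.23, adjusted p = 9.28e-08). For shRNA1 it passed without shRNA1 replicate 2 (adjusted p = 0.0287) and, as a fall, with quantile normalization (median -0.11, adjusted p = 0.00186; range over all settings 0.00186 to 0.652). For shRNA3 its call ended with quantile normalization (median 0.0066, adjusted p = 0.396) and with an estimated correlation (adjusted p = 0.324; range over all settings 9.26e-10 to 0.396). Rps2 and Rpl22 rose 1.32-fold and 1.22-fold. Rps27 rose 1.98-fold from 5.32 ± 0.409 FPKM, a level far below that of Rps2, and is uncertain because such genes share reads with processed copies. Adjusted over the list alone, counts differed for 6 lists: 4 epithelial and 8 DNA replication genes fell, 14 protease, 11 MHC class I and 23 ribosomal protein genes rose, and 12 chemokine and cytokine genes rose and 8 fell.

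**Figure D2:**
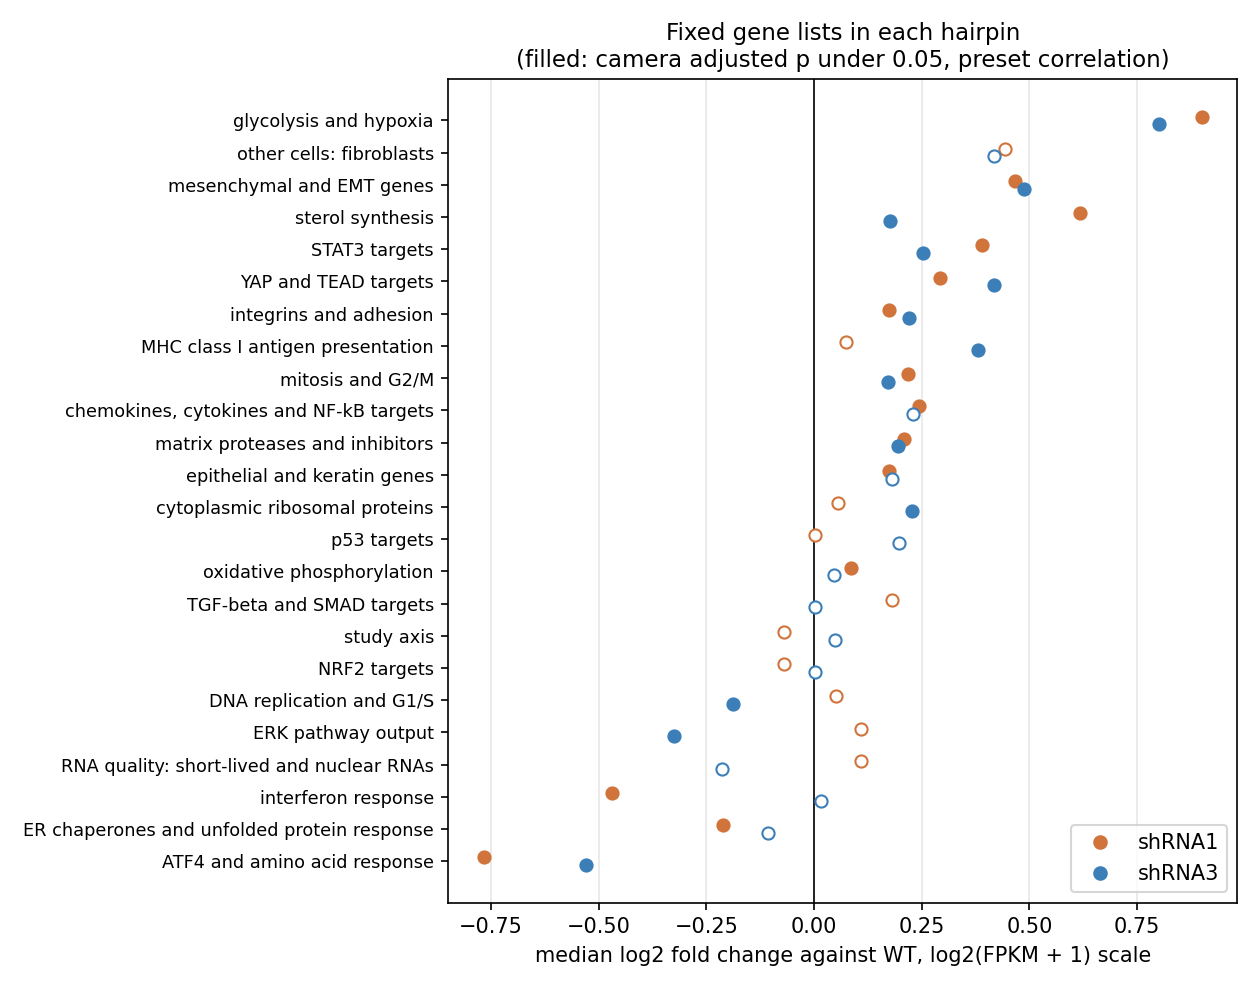
Median log2 fold change of the tested members of each gene list against WT, on the log2(FPKM + 1) scale, with shRNA1 in orange and shRNA3 in blue; filled points passed camera with a preset correlation. The ATF4 and amino acid response list lay at -0.77 and -0.53, and glycolysis and hypoxia at 0.90 and 0.80, while interferon response lay at -0.47 with shRNA1 and 0.02 with shRNA3.

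The remaining lists did not pass camera over both hairpins, although single members passed limma. Of all genes tested 50.0% were called over both hairpins, 36.0% with shRNA1 and 55.2% with shRNA3. Counts of called members near these shares do not set a list apart from other genes. Of the ERK pathway output genes 9 of 28 rose and 12 fell (median -0.08, camera adjusted p = 0.389), with Fos 3.66-fold and Ier3 2.10-fold higher and Hmga2 1.87-fold lower. Among DNA replication genes 2 of 26 rose, E2f1 among them, and 9 fell, including Tyms and Fen1 (adjusted p = 0.147). For oxidative phosphorylation 10 of 26 rose and 3 fell, with Cox6c and Uqcrfs1 higher and Cycs lower (adjusted p = 0.293). In the list of chemokines, cytokines and NF-kB targets 11 of 22 rose and 6 fell, with Ptgs2 2.45-fold, Tnfaip3 1.95-fold and Ccl7 2.13-fold higher (adjusted p = 0.0659). Rescaling to the same total made a call of the list of chemokines, cytokines and NF-kB targets (adjusted p = 0.0453; range over all camera settings 0.0453 to 0.221), and fry, on the list alone, gave 4.70e-05. Among p53 targets 7 of 18 rose and 5 fell, with Plk2, Cdkn1a and Btg2 1.72-fold, 1.70-fold and 1.99-fold higher (adjusted p = 0.208). For NRF2 targets 5 of 22 rose and 7 fell, with Srxn1, Fth1 and Gclc lower (adjusted p = 0.411), and for TGF-beta and SMAD targets 6 of 15 rose and 5 fell, with Id2 and Ctps higher and Id1 lower (adjusted p = 0.391). Fos, Hmga2, Irf7, Bst2, S100a8, Tgfb2, Fdps, Hmgcs1, Aurkb, Mapk3, Rpl22, E2f1, Tyms, Fen1, Cycs, Cox6c, Uqcrfs1, Ccl7, Cdkn1a, Btg2, Gclc, Id1 and Ctps, with Braf and Snora44 named above, lost their calls when the 4 knockdown libraries were fitted as 1 group. Taken alone, shRNA1 gave no call of Braf, Tyms, Fen1, Cycs and Id1, and shRNA3 none of E2f1, Btg2, Gclc and Snora44.

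Markers of other cell types were mostly silent. Of 25 leukocyte markers 3 passed the filter: Cd68, a lysosomal protein gene that carcinoma cells can also express, rose 3.41-fold, S100a8 fell 2.16-fold and the other did not pass the test. Of 16 fibroblast markers 7 passed the filter, and 4 rose and 2 fell (camera adjusted p = 0.147), with Dcn 3.80-fold and Gsn 2.23-fold higher and Pi16 2.81-fold lower. These changes stand beside those of the mesenchymal list. Of 15 endothelial and muscle markers, Egfl7 alone passed the filter, at a log2 change of 0.10 (limma, Benjamini-Hochberg adjusted p = 0.114), and none of the red cell markers passed it. The symbols of the mitochondrial transcripts were not among those used here. Of 9 short-lived or nuclear RNAs, read as a sign of RNA handling, 4 rose and 5 fell (camera adjusted p = 0.877). All 9 were thus called, against 50.0% of all genes tested. Camera looks for 1 shared direction, so it cannot exclude a handling difference that moves such RNAs both ways. Jun rose 1.79-fold, and Snhg1 and Snhg12, hosts of small nucleolar RNAs, fell 1.65-fold and 1.58-fold, the last 2 with a loss of the call when the knockdown libraries were fitted as 1 group.

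With shRNA1 alone, the ATF4 response fell furthest. Of its 31 genes 29 fell and 1 rose (median -0.77, camera adjusted p = 2.01e-20; adjusted p = 0.0506 with an estimated correlation), and Ddit3, the gene of CHOP, fell from 104 ± 1.90 to 33.0 ± 2.35 FPKM. Interferon response genes fell in 26 of 36 cases with 0 rises (median -0.47, camera adjusted p = 5.92e-11), sterol synthesis genes rose in 24 of 24 cases (median 0.62, adjusted p = 2.82e-17) and glycolysis and hypoxia genes in 28 of 30 (median 0.90, adjusted p = 6.40e-26). These 3 lists also passed with an estimated correlation (adjusted p = 0.0419 for each), and no list did so in the other 3 comparisons. Adjusted over the list alone, 29 interferon response genes fell and 1 rose, and 29 glycolysis and hypoxia genes rose. Egr1, an immediate early gene, rose from 1.72 ± 0.0771 to 15.9 ± 0.559 FPKM, beside Krt19 and Steap4. The largest falls included Ifi27l2a, Snora44 and Mir1291, the last 2 on the few fragments given above, and Ndufs5, a gene of complex I with processed copies. The call of Snora44 ended without any of the 4 libraries compared (adjusted p from 0.0503 to 0.0602). Ndufs5 is uncertain: the SD of its WT libraries was 8.54 FPKM, it was at 0.002 FPKM in both shRNA1 libraries, and its call ended without WT replicate 2 (adjusted p = 0.0584; range over all settings 0.00218 to 0.134). In all 1954 genes were higher and 2035 lower with shRNA1 than in WT (limma, Benjamini-Hochberg), 103 and 35 of them at least 2-fold, and 14 of 24 lists passed camera. The other 10 of these lists, among them endoplasmic reticulum chaperones (median -0.21) and STAT3 targets (median 0.39), had adjusted p from 0.0506 to 0.511 with an estimated correlation. The number of lower genes was 1320 without WT replicate 1, 1333 without WT replicate 2, 1339 without shRNA1 replicate 1 and 1322 without shRNA1 replicate 2. After rescaling to the same total, 35.6% of the called genes were higher, against 49.0%.

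With shRNA3 alone, the ATF4 response fell in 26 of 31 genes and rose in 2 (median -0.53, camera adjusted p = 2.77e-09; adjusted p = 0.226 with an estimated correlation), and glycolysis and hypoxia genes rose in 28 of 30 cases (median 0.80, adjusted p = 5.57e-15; adjusted p = 0.217 with an estimated correlation). ERK pathway output genes fell in 17 of 28 cases and rose in 4 (median -0.32, adjusted p = 0.00284; adjusted p = 0.229 with an estimated correlation). Among them Dusp6, Etv5 and Ccnd1, picked after their values were seen, fell 2.15-fold, 2.28-fold and 1.71-fold. DNA replication genes fell in 16 of 26 cases (median -0.19, adjusted p = 9.86e-04; adjusted p = 0.226 with an estimated correlation). Adjusted over the list alone, 27 ATF4 response genes fell, and the counts of the other 3 lists were the same. Interferon response genes rose in 12 of 36 cases and fell in 7 (median 0.02, adjusted p = 0.480). Gadd45b rose from 4.99 ± 0.659 to 47.3 ± 1.47 FPKM, beside Ptx3 and Nos2. S100a8 fell from 78.6 ± 9.67 to 10.9 ± 0.231 FPKM and Mt2, a metallothionein gene, from 123 ± 0.996 to 24.5 ± 0.267. Snora31 also ranked among the falls, from 2 fragments in each WT library to none, and its call ended without any of the 4 libraries compared (adjusted p from 0.0575 to 0.0843; range over all settings 9.82e-11 to 0.171). In all 3036 genes were higher and 3075 lower with shRNA3 than in WT (limma, Benjamini-Hochberg), 166 and 86 of them at least 2-fold, and 13 of 24 lists passed camera. The other 9 of these lists, among them YAP and TEAD targets (median 0.42) and ribosomal protein genes (median 0.23), had adjusted p from 0.226 to 0.324 with an estimated correlation. After rescaling to the same total, 37.8% of the called genes were higher, against 49.7%.

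The hairpins were then compared with each other, which tests their difference itself. Egr1 was at 15.9 ± 0.559 FPKM with shRNA1 and 0.760 ± 0.274 with shRNA3, Mt2 at 179 ± 4.64 and 24.5 ± 0.267, and S100a8 at 61.8 ± 0.483 and 10.9 ± 0.231. The genes with the largest positive difference were Ptgds, the prostaglandin D synthase (2.29 ± 0.629 with shRNA1 and 11.2 ± 2.90 with shRNA3), Defb25, the ligand gene Wnt6 (4.34 ± 0.183 and 14.7 ± 0.438) and Ddit3 (33.0 ± 2.35 and 98.7 ± 7.68). The call of Defb25 ended without shRNA3 replicate 1 (adjusted p = 0.0784; range over all settings 2.88e-04 to 0.130). Mir8091 ranked first among the negative differences but rested on 1 fragment in each shRNA1 library and none in the shRNA3 libraries, and its call ended without any of these 4 libraries (adjusted p from 0.105 to 0.135). Interferon response genes were higher with shRNA3 than with shRNA1 in 32 of 36 cases (median 0.48, camera adjusted p = 7.20e-14; adjusted p = 0.0622 with an estimated correlation). ERK pathway output genes were lower in 21 of 28 cases and higher in 2 (median -0.50, adjusted p = 3.42e-09; adjusted p = 0.0776 with an estimated correlation). Sterol synthesis genes were lower in 22 of 24 cases (median -0.53, adjusted p = 3.97e-10; adjusted p = 0.0622 with an estimated correlation), and DNA replication genes in 19 of 26 (median -0.33, adjusted p = 5.33e-07; adjusted p = 0.0764 with an estimated correlation). The ATF4 response was higher with shRNA3 in 22 of 31 cases and lower in 4 (median 0.34, adjusted p = 9.16e-07; adjusted p = 0.254 with an estimated correlation). Adjusted over the list alone, 34 interferon response genes were higher, 22 ERK pathway output genes lower, 19 DNA replication genes lower and 1 higher, and 23 ATF4 response genes higher. MHC class I genes (median 0.36), ribosomal protein genes (median 0.18), endoplasmic reticulum chaperones (median 0.22) and YAP and TEAD targets (median 0.26) were also higher with shRNA3 by camera (each adjusted p = 0.455 with an estimated correlation). Between the hairpins 2440 genes were higher and 2273 lower in shRNA3 (limma, Benjamini-Hochberg), 41 and 67 of them at least 2-fold. Together these were 42.5% of all genes tested, the share to set beside the counts of list members above.

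**Figure D3:**
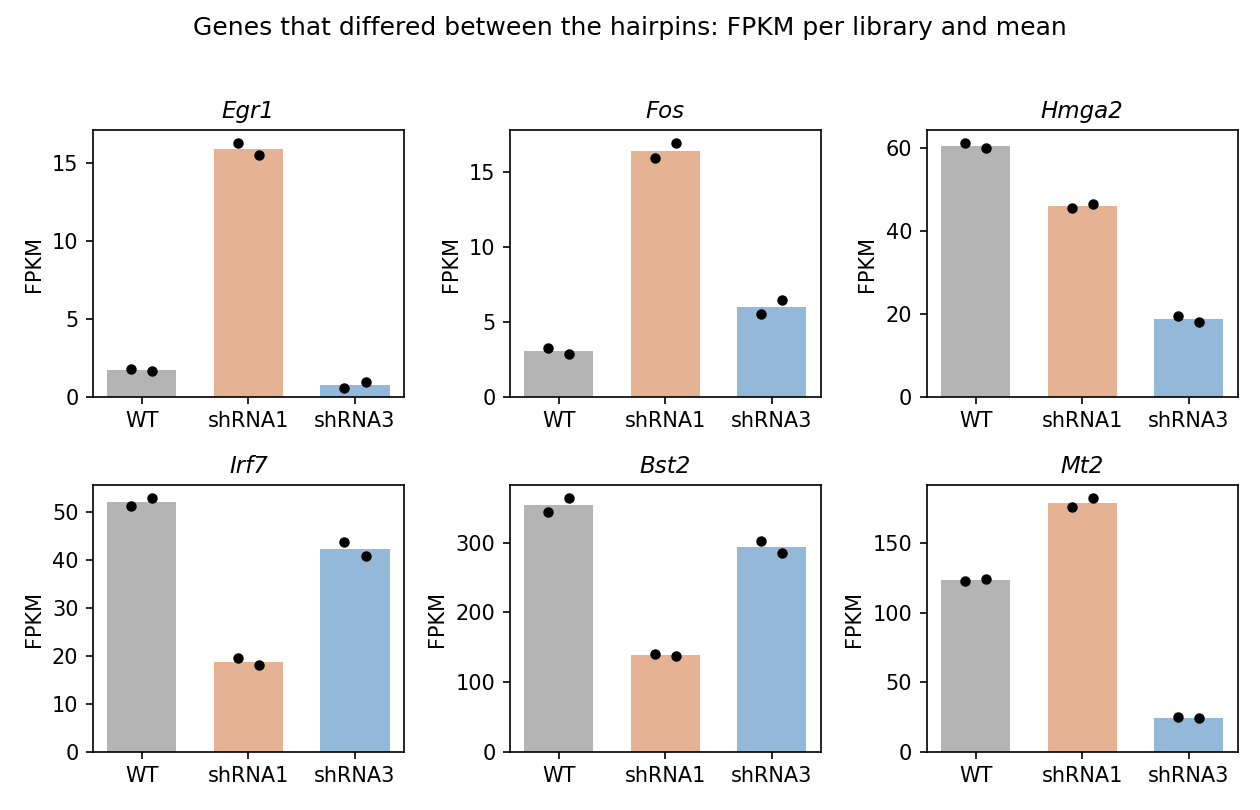
FPKM of Egr1, Fos, Hmga2, Irf7, Bst2 and Mt2 in each library (points) with the mean of each group of 2 libraries (bars); each panel has its own linear axis from 0. Egr1 stood at 15.9 FPKM on average with shRNA1 and 0.760 with shRNA3, and Irf7 and Bst2 were lowest with shRNA1.

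The overlap of the hairpins was counted gene by gene. Both called 1349 genes higher and 1343 lower, Trib3, Atf5, Slc2a3, Mmp9 and Krt19 among them, while 118 genes were higher with shRNA1 and lower with shRNA3, and 108 the reverse. Egr1, Mt2 and Csf3, the last picked after its values were seen, were among the genes higher with shRNA1 and lower with shRNA3. Simulated groups with no effect, compared with the same simulated WT libraries, gave a mean of 0.13 genes called higher and 0.2 called lower by both. Independent lists of the observed lengths would share 535 and 565. In the simulation all 6 libraries were drawn as independent noise per gene, with the spread within groups. The draws hold no correlation between genes and no deviation shared by the libraries of a group. They do not show how many shared calls such deviations would give. Across genes, which are not independent replicates, the log2 changes of the hairpins had a correlation of 0.638, against 0.491 in the simulation, and a covariance of 0.0991, against 0.00756, a difference of 0.0915. No split of the 2 WT libraries leaves 2 for each hairpin, so part of the excess over independent lists may come from the shared controls. The number called lower by both was 842 without WT replicate 1 and 882 without WT replicate 2.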

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

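The tests below of scaling, of an off-target effect, of nutrient depletion and of handling at harvest were chosen after the results were seen, and those of GC content and transcript length before.

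The hairpins were compared with each other by limma, and each difference given here, as log2 of shRNA3 minus shRNA1 over 2 libraries each, passed that test. Of 98 named genes 76 differed, 19 of them at least 2-fold, and Egr1, Mt2 and Ptgds were called in opposite directions by the hairpins. Part of the named genes were selected for a large difference in this same comparison, so the selection raises this share. Of all 11079 genes tested 42.5% differed. Lower with shRNA3 were Egr1 (-3.27), Mt2 (-2.82), S100a8 (-2.40), Fos (-1.32), Id1 (-1.28) and Hmga2 (-1.25). Higher with shRNA3 were Tgfb2 (1.05), Bst2 (1.07), Atf5 (1.08), Irf7 (1.13), Trib3 (1.24), Ifi27l2a (1.30), Ccl7 (1.35), Gadd45b (1.45), Ddit3 (1.55), Wnt6 (1.56) and Ptgds (1.88). The 19 include Mir8091, for which no size is given: it rested on 2 fragments in the hairpin libraries, too few to show a change, and its call ended without any of these 4 libraries (adjusted p from 0.105 to 0.135). Defb25 differed by 1.83 with a call that ended without shRNA3 replicate 1 (adjusted p = 0.0784). By camera with a preset correlation 9 lists differed, with medians of 0.48 for interferon response, 0.36 for MHC class I antigen presentation, 0.34 for the ATF4 and amino acid response, 0.26 for YAP and TEAD targets, 0.22 for endoplasmic reticulum chaperones, 0.18 for ribosomal proteins, -0.33 for DNA replication, -0.50 for ERK pathway output and -0.53 for sterol synthesis. With an estimated correlation none of the 9 passed.

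ATF4 and amino acid response genes were lower with both hairpins. Scaling of the libraries was excluded as the whole cause, since the median nearest to 0 under median-of-ratios, quantile and equal-total scaling was -0.67. GC content and transcript length, known for 96.8% of the members, explained 1.46% of the variance of the changes, and removing their trend left a median of -0.66, which argues against them as the whole cause. Of the 31 genes 29 were called lower with shRNA1 and 26 with shRNA3, and the median was -0.53 in shRNA3, the hairpin with the smaller fall. These values argue against an off-target effect of 1 hairpin as the whole cause but do not exclude it. Both hairpins were compared with the same WT libraries, so a deviation of those libraries would enter both sets of calls. As a list, neither hairpin's fall passed with an estimated correlation (adjusted p = 0.0506 for shRNA1 and 0.226 for shRNA3). An off-target effect of each hairpin, or of 1 hairpin on the size of its fall, was not tested. A lower ATF4 activity after loss of AU021063 is a hypothesis that may account for it, but effects of hairpin delivery or culture that both knockdown lines share against mock transfected cells stay open, as the labels name no non-targeting hairpin.

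Glycolysis and hypoxia genes were higher with both hairpins. Scaling left a median of at least 0.79 under the 3 settings, and removing the trend on GC content and transcript length, known for 96.7% of the members, left 0.83, so neither accounts for the rise as a whole. Depletion of amino acids or glucose in denser knockdown cultures could raise some of these genes and would also raise an intact ATF4 response. The median of the ATF4 list was -0.68. Whether the knockdown cells could still raise that response was not tested, so this value does not exclude depletion. Lower oxygen around denser cells, an effect of hairpin delivery and an effect of AU021063 loss on HIF-1 targets stay open and were not tested, since the labels give neither cell density nor culture times.

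ERK pathway output genes were lower with shRNA3 than with shRNA1. Against WT, 10 of 28 rose and 8 fell with shRNA1, and the list did not pass (median 0.11, camera adjusted p = 0.0800). With shRNA3, 4 rose and 17 fell (median -0.32, camera adjusted p = 0.00284, and 0.229 with an estimated correlation). Under the 3 scalings the median difference nearest to 0 was -0.48, which excludes scaling as the whole cause. Egr1, Fos and other genes induced within minutes could differ through handling at harvest, and the 8 rapid members had a median difference of -0.98. The 20 slower members had a median of -0.47, with 16 called lower and 1 higher. Handling that acts on rapid genes alone therefore does not account for the difference as a whole. Handling that also acts on the slower members was not tested. Against WT the rapid members had medians of 0.79 with shRNA1 and 0.09 with shRNA3, and the slower members 0.02 and -0.38. An off-target effect of either hairpin, or a difference between the cell lines made with them, stays open, since the labels do not give how many lines were made with each hairpin.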

How the results depend on the processing

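The fit without miRNA and snoRNA genes was chosen after seeing the data, the other settings before. Of 113 named gene results, set against 19 settings in 2130 pairs, 2063 had the same direction and side of the threshold, 57 were weaker, 5 stronger and 5 reversed. Fitting only the groups compared, which for both hairpins puts differences between them into the spread, ended 27 named calls and left 798 genes higher and 715 lower. At a minimum of 2-fold 97 and 24 genes passed for both hairpins, 103 and 35 for shRNA1, 166 and 86 for shRNA3, 41 and 67 between the hairpins, and 55 and 8 were called by both, since fewer changes are that large. With libraries left out in turn, which leaves a lone library assumed to vary like the others, 1320 to 1888 genes were lower with shRNA1 and 842 to 1138 were called lower by both. Rescaling to the same total gave 1993 higher and 3747 lower for both hairpins, 1491 and 2693 for shRNA1, and 2372 and 3908 for shRNA3, with a median of all genes of -0.07 for both. AU021063 had a log2 change of -0.83, -1.04 to -0.62 with libraries left out, -1.85 and -1.15 with pseudocounts of 0.1 and 0.5, which compress low values less, and -1.12 rescaled, where it passed the filter (adjusted p = 0.0116); without a filter adjusted p was 0.0542, and quantile normalization gave no value. With an estimated correlation 0 lists passed for both hairpins, 3 for shRNA1, 0 for shRNA3 and 0 between them. With fry, which tests lists on their own, 22 passed for both, 21 for shRNA1, 20 for shRNA3 and 16 for the difference. With camera at the preset correlation these numbers were 14, 14, 13 and 9. The direction of the set test turned, while the cause was not tested, for the study axis from up to down at a mean of at least 5 FPKM (median -0.038), with quantile normalization (0.022), with fry (-0.0050, its median as reported) and without shRNA1 replicate 1 (-0.0068, in a range of -0.046 to 0.00054 with libraries left out), and for short-lived RNAs from down to up with fry (-0.16, as reported). With quantile normalization both the direction and the median turned for oxidative phosphorylation (-0.045) and ribosomal proteins (-0.044). Log2 changes near 0 reversed for Il6ra at 0.022 (quantile) and -0.046 to 0.036 with libraries left out and for Rfwd2 at -0.039 (rescaled) and -0.045 to 0.095 with libraries left out. Settings for counts were not run, as the files hold no counts, nor was camera with only the groups compared.

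Deviations of libraries with the same replicate number had correlations across genes of 0.0103 for WT and shRNA1 and -0.0719 for WT and shRNA3. For shRNA1 and shRNA3 the correlation was 0.199. The numbers thus show little pairing of WT with the hairpins, while a pairing between the hairpins cannot be ruled out. With the replicate block 2499 genes were higher and 2706 lower for both hairpins, 1749 and 1774 for shRNA1, 2872 and 2925 for shRNA3, and 2209 and 2099 between the hairpins. Over both hairpins it changed no call of a named gene or list; oxidative phosphorylation with shRNA1 went from adjusted p = 0.0466 to 0.0524 and proteases with shRNA3 from 0.0492 to 0.0534. Depth limits the low genes, such as AU021063 with 35 fragments in all and Il6 with 71.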

Other observations

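The genes and tests in this part were chosen after their values were seen. Mt1, a metal-binding protein gene, was at 168 ± 15.1 FPKM in WT, 324 ± 15.3 with shRNA1 and 107 ± 3.40 with shRNA3 (n = 2 libraries each), and Csf3, the gene of the granulocyte colony-stimulating factor, was at 116 ± 1.21, 188 ± 0.926 and 38.2 ± 0.319. Both differed between the hairpins, at log2 differences of -1.59 and -2.27 (limma adjusted p = 7.58e-06 and 4.88e-08). Txnip, an inhibitor of glucose uptake, rose 1.16-fold with shRNA1 and 2.96-fold with shRNA3. Sele, the gene of E-selectin, fell from 3.63 ± 0.276 to 2.30 ± 0.380 and 0.270 ± 0.0474 FPKM.

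The coding genes next to AU021063 on chromosome 15 showed no called change over both hairpins. Acvr1b, an activin receptor gene, had a log2 change of 0.08 (adjusted p = 0.247), Grasp 0.11 (adjusted p = 0.225) and the nuclear receptor gene Nr4a1 0.03 (adjusted p = 0.667). With shRNA1 alone Acvr1b was 1.18-fold higher (adjusted p = 0.0239). The overlapping antisense gene A330009N23Rik was at 0.690 ± 0.0523 FPKM in WT, 0.690 ± 0.0375 with shRNA1 and 0.367 ± 0.257 with shRNA3, below the filter.

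One hypothesis was that Trib3 RNA falls alone, apart from other ATF4 targets. Without Trib3 the other 30 tested members of the list had a median log2 change of -0.66 (camera adjusted p = 2.55e-14; adjusted p = 0.132 with an estimated correlation). Of these 30 genes 27 were called lower one by one, so the data exclude a change of Trib3 alone, although Trib3 had the lowest value of the 31. RNA levels of this kind do not measure the stability of the Trib3 RNA or protein.

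Another hypothesis was that the fall of the ATF4 list is graded with the loss of AU021063. The list was higher with shRNA3 than with shRNA1 by a median of 0.34, while AU021063 had 9 fragments with shRNA1 and 5 with shRNA3. These numbers may come from equal levels (exact binomial p = 0.289, two-sided), so a graded fall cannot be told apart from its absence with so few fragments of AU021063.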
